A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

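RNA abundance was measured by strand-specific sequencing of total RNA from which ribosomal RNA had been removed, in Saccharomyces cerevisiae strain BY4742 (WT, a MATα laboratory strain) and in the same strain without SET2 (set2Δ). SET2 encodes the histone methyltransferase that places methyl groups on lysine 36 of histone H3. Per the labels' protocols, log-phase cultures in rich medium (YPD) were pelleted, washed with water and moved to SD, a synthetic medium, and cells were taken at 0, 30, 60 and 120 min after the shift. Which supplements the SD medium held is not given in the sources used here. RNA came from an acid phenol extraction followed by DNase treatment, and the libraries from a stranded total RNA kit used with a yeast rRNA depletion kit. The 24 libraries comprise 4 of WT at 0 min, 2 of set2Δ at 0 min, and 3 of each genotype at 30, 60 and 120 min.

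The authors deposited 1 table of RPKM values (reads scaled by gene length and by the total of the library), with 1 column per library and a listed length for each of 6571 genes. Per the submitters' processing notes, Bowtie 1.1.2, SAMtools 1.3.1, bedtools 2.25.0 and DESeq2 1.6.3 were used with the sacCer3 build. The notes used here give these tools no role. The strand setting of the counting, any removal of duplicate reads, and the annotation are not given in the sources used here, so values of genes that overlap on opposite strands, and of near-identical copies, are uncertain. Of the 6571 gene names, 5897 matched the RefSeq annotation of assembly R64, and coordinates are those of its coding sequences (1-based, first to last base). The listed length equalled the R64 coding length less 1 base per exon part for 5886 of these, so lengths are coding lengths. The other 674 names, mostly frames now regarded as dubious, were not in that annotation and have no coordinates here. Every column of the table was used, and 130 genes were listed at 0 in every library.

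Each RPKM value multiplied by gene length gave a whole multiple of 1 step per library, within 0.05 of a whole read for 100.0% of values. The steps gave library totals of 2201243 to 4519162 reads, of which 86.05% to 91.39% lay in listed genes. For a gene of 1 kb, the 3 reads that a count of 0 allows at 95% confidence correspond to between 0.664 RPKM in the deepest library and 1.363 RPKM in the shallowest. Such floors cover counting error only. Among genes over 500 bp, no library passed 2.035 reads per base, whatever its depth. The highest RPKM of a gene over 500 bp was 430.8 in the library of 4519162 reads and 706.9 in the library of 2201243 reads. What set this ceiling is not given in the sources used here, and it compresses differences between libraries for the most abundant genes. In RPKM it lies lower in deeper libraries (r = -0.95 between total reads and the highest RPKM of genes over 500 bp). It can thus also bring apparent decreases of abundant genes in deeper libraries. The WT libraries at 0 min were shallower than every later WT library but replicate 3 at 30 min.

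Replicates were compared before any test, by a chi-square statistic per gene on the recovered reads. WT 0 min replicates 1 and 2 gave 0.86 and replicates 3 and 4 gave 0.76, less than sampling noise, while other pairs within a group reached 21.91. Each of these pairs was therefore averaged and counted as 1 sample, so WT at 0 min has n = 2 and the tests used 22 units. This departs from the design written before the data were examined, which entered 24 separate libraries, and the fit with 24 is among the alternatives. Replicate numbers come from the labels. At 120 min all 3 pairs of WT and set2Δ libraries with the same number deviated together from their group means (r = 0.14 to 0.25, other pairs -0.21 to 0.02), so that comparison was taken as paired, and a fit with the number as a block within 120 min was added after the data were seen. At 0, 30 and 60 min the lowest same-number correlation was -0.03, 0.04 and 0.05, under the bound of 0.1 used, and those comparisons were not taken as paired. At 60 min the same-number pairs (0.05 to 0.20) still all lay above the other pairs (-0.16 to -0.01). At 30 min they ran from 0.04 to 0.33, against -0.27 to 0.12 for the other pairs. A weaker pairing at 30 and 60 min is thus not excluded. At 0 min the deviations of the 2 set2Δ libraries mirror each other, so the correlations there could hardly show a pairing. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

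From the deposited RPKM values, log2(RPKM + 1) was computed and tested with limma 3.58.1 in R 4.3.3. Genes with an RPKM of at least 1 in at least 2 libraries were kept, which left 6387. One linear model held a mean for each of the 8 groups (14 residual degrees of freedom), with empirical Bayes moderation along an intensity trend. Adjusted p is limma's p after the Benjamini-Hochberg procedure over the genes tested, and genes under 0.05 were called. Log2 changes are on the log2(RPKM + 1) scale, which understates changes of low genes. The 14 comparisons were set2Δ minus WT at each time and averaged over the 4 times, each later time minus 0 min within each genotype, and the interaction (the time change in set2Δ less that in WT). DESeq2 was not used here. The authors' table holds RPKM values, and the reads recovered from them were tested with limma voom as an alternative. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots made with matplotlib 3.10.9.

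The model, the filter, the 14 comparisons, the alternative settings, 34 gene lists and the rule for named genes were chosen before the data were examined. The rule took SET2 everywhere. For set2Δ minus WT at each time and for the WT time changes it took the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 5 RPKM in the higher group and no overlap between the libraries of the groups. It took 5 per direction for each interaction, up to 4 members of each list described, and every tested member of the control lists (genes deleted in BY4742, a-cell genes and α-cell genes). The set2Δ time changes used the genes named for WT. One run of all comparisons and lists was looked at before it was decided which lists to describe in which comparison, so that choice was made after results were seen.

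Lists were tested with limma's camera with a preset correlation of 0.01 between genes, and again with the correlation estimated for each list. Beside a list's camera p stands the adjusted p with an estimated correlation. The count adjusted over the list alone applies the Benjamini-Hochberg procedure to the members only. Of the 95 results described from lists fixed beforehand, 84 lost their call with an estimated correlation and 7 had no call to lose. The other 4, those of the genes used to assay cryptic initiation at 30, 60 and 120 min and for the mean of the 4 times, kept it. The pheromone response list, written after the data were seen, lies outside the 95. Its p with an estimated correlation, not adjusted over lists, was 0.018 and 0.019 in WT at 60 and 120 min and 0.037 and 0.027 in set2Δ. Among list results not described further, 3 also kept their call, all for set2Δ minus WT at 30 min: the iron regulon (p = 0.016 with an estimated correlation), the set of genes not in RefSeq (p = 0.037) and the genes covered by a gene on the other strand (p = 0.037).

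Alternative settings fixed then were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, median-ratio and quantile normalization, moderation without a trend, array weights, fits on only the groups compared, leaving out each library in turn, and the replicate number as a block. Added after the data were seen were the 24 separate libraries, limma voom on the recovered reads, an occupancy correction that assumes a ceiling of 2.14 reads per base, the results without WT 30 min replicate 3, the set of genes not in RefSeq, and the 15 genes left by the filter out of 16 covered by a gene on the other strand. On simulated data for 6387 genes, with 100 genes changed per fold size, the model called 93 of 100 genes changed 2-fold and 99 of 100 changed 4-fold for set2Δ minus WT at 60 min, and 9 of 6187 unchanged genes. For the change in set2Δ at 60 min it called 89 and 98 of 100 and 13 unchanged genes, and for the interaction at 60 min 76 and 94 of 100 and 11 unchanged genes. In the simulated WT change at 60 min, where nothing differed, none of 6387 genes was called by limma. The simulated noise was independent between libraries, with a capped spread equal in all groups and no ceiling on reads. Only 200 genes changed, all drawn from above a low mean level. The real libraries differ from this, with unequal spread between groups, so these rates are not the error rates of the real comparisons.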

Results

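RNA levels were measured in wild-type (WT) and set2Δ yeast taken at 0, 30, 60 and 120 min after transfer from rich YPD medium to synthetic SD medium. The series asked how loss of H3K36 methylation, the mark placed by Set2, alters the transcriptional response to this nutrient stress. The 24 libraries held between 2201243 reads (WT at 30 min, replicate 3) and 4519162 reads (WT at 30 min, replicate 1). WT at 0 min had 4 libraries that formed 2 pairs, replicates 1 with 2 and 3 with 4, whose members differed by less than the sampling noise. Each pair was counted as 1 sample, so n = 2 for both genotypes at 0 min and n = 3 elsewhere.

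The deleted gene was examined first. SET2 (YJL168C, R64 chromosome X, 102227 to 104428, coding sequence) stood at 92.1 ± 3.9 RPKM (SD, n = 2) in WT at 0 min and at 92.2 ± 2.5, 84.4 ± 0.3 and 77.0 ± 1.9 RPKM (SD, n = 3 each) at 30, 60 and 120 min. In set2Δ it was at 0.2 ± 0.2 RPKM (SD, n = 2) at 0 min and at 0.3 ± 0.1, 0.3 ± 0.3 and 0.0 ± 0.1 RPKM (SD, n = 3 each) later. The log2 differences were -6.35, -6.21, -6.12 and -6.23, with adjusted p (limma) from 2.6e-12 to 1.0e-13. YJL169W, a dubious frame that overlaps SET2 on the other strand, was lower in set2Δ at every time (-4.14, -3.37, -3.89 and -3.86). In WT, SET2 itself did not pass the test after the shift (log2 change 0.00, -0.12 and -0.25 with adjusted p = 1.0, 0.63 and 0.3).

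The auxotrophic markers of BY4742 were read as a strain check. LEU2, LYS2 and URA3, deleted in this background, were listed at 0 in all 24 libraries. HIS3, of which only a part is deleted in BY4742, was at 136 ± 23.3 RPKM (SD, n = 2) in WT at 0 min and rose by 0.68, 0.83 and 0.88 on the log2 scale at 30, 60 and 120 min (adjusted p = 6.5e-05, 7.1e-06 and 3.1e-06, limma). In the principal components of all genes, the first component (44.4% of the variance) placed the 0 min libraries apart from the later ones and the second (16.9%) placed the genotypes apart. WT at 30 min replicate 3 lay at 14.46 on the first component, against -16.93 and -5.76 for the other two libraries of its group.

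**Figure D1:**
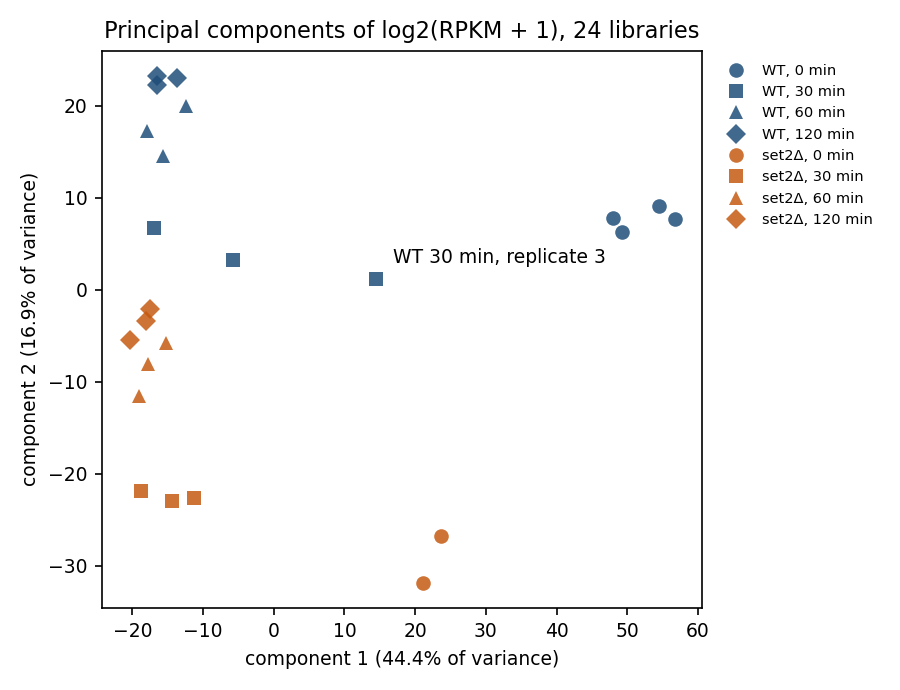
Principal component scores of log2(RPKM + 1) for the 24 libraries, with component 1 (44.4% of the variance) on the horizontal axis and component 2 (16.9%) on the vertical axis. Each point is 1 library, its colour the genotype and its shape the time, and WT at 30 min replicate 3 lies at 14.46 on component 1, between the 0 min libraries and the other libraries of its group.

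The change in WT after the shift answered how normal cells respond to the poorer medium. Many genes for scavenging nitrogen rose, among them DAL80 (XI, 506898 to 507707), a GATA repressor of nitrogen catabolic genes, from 3.9 ± 1.5 RPKM (SD, n = 2) to 152 ± 18 RPKM at 30 min (SD, n = 3). DAL80 rose by 5.01, 5.16 and 5.24 on the log2 scale at 30, 60 and 120 min. Many genes of sulfate assimilation and amino acid synthesis rose as well. In contrast, most ribosomal protein and ribosome biogenesis genes fell. Of 6387 genes tested, limma called 3229 at 30 min (1619 up, 1610 down), 3871 at 60 min (1772 up, 2099 down) and 3959 at 120 min (1758 up, 2201 down). A fit on only the groups compared called 1076 at 30 min.

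In the list of genes under nitrogen catabolite repression, 27 of 33 rose and 1 fell at 30 min (27 and 1 adjusted over the list alone). The median log2 change was 1.12 (camera adjusted p = 1.3e-12, adjusted p = 0.22 with an estimated correlation). At 60 and 120 min 25 rose at each time and 3 and 6 fell (26 rose and 3 and 6 fell adjusted over the list alone), with medians of 1.11 and 1.02 (adjusted p = 0.47 and 0.42 with an estimated correlation). DAL3, an enzyme of allantoin breakdown (IX, 415030 to 415617), rose by 3.71 ± 0.12 (SE) at 30 min, MEP2, an ammonium permease (XIV, 357453 to 358952), by 3.18 ± 0.17, and GAP1, the general amino acid permease (XI, 515063 to 516871), by 3.24 ± 0.29. GAP1 went from 50.9 ± 39.9 RPKM (SD, n = 2) to 413 ± 57.2 RPKM (SD, n = 3). SEO1, a putative permease (I, 7235 to 9016), rose by 4.92 at 30 min from 4.4 ± 2.3 RPKM (SD, n = 2).

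Of 27 genes of methionine and sulfur assimilation, 26 rose at 30 min and none fell (27 and 0 adjusted over the list alone), with a median of 1.90 (camera adjusted p = 7.2e-20, adjusted p = 0.22 with an estimated correlation). At 60 and 120 min 23 rose at each time and 0 and 1 fell (23 at each rose and 0 and 2 fell adjusted over the list alone), and the medians were 1.77 and 1.39 (adjusted p = 0.46 and 0.42 with an estimated correlation). MET5 and MET10, the subunits of sulfite reductase, rose by 2.75 and 2.64 at 30 min, MET1, an enzyme of siroheme synthesis, by 2.92, and SUL2, a sulfate permease, by 2.74. Among 56 amino acid biosynthesis genes under Gcn4, 42 rose and 3 fell at 30 min, 48 and 3 at 60 min, and 47 and 2 at 120 min (43 and 3, 48 and 4, 48 and 4 adjusted over the list alone), with medians of 0.72, 0.90 and 0.88 (adjusted p = 0.35, 0.47 and 0.42 with an estimated correlation). The largest change in that list was that of SNO1 (XIII, 457285 to 457959), which rose by 4.05, 5.52 and 5.61 and, like its neighbour SNZ1 (1.81, 2.85 and 2.93), acts in vitamin B6 synthesis. At 30 min SNO1 was at 183, 159 and 21.6 RPKM in WT replicates 1, 2 and 3, and without replicate 3 the changes were 5.03 for SNO1 and 2.46 for SNZ1. ARG3, ornithine carbamoyltransferase of arginine synthesis (X, 268799 to 269815), rose by 2.56, 3.30 and 3.38.

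At 30 min 78 of 78 ribosome biogenesis genes fell (78 adjusted over the list alone), with a median of -1.88 (camera adjusted p = 6.8e-27, adjusted p = 0.35 with an estimated correlation). At 60 and 120 min 70 and 61 fell (71 and 63 adjusted over the list alone), with medians of -1.09 and -0.86 (adjusted p = 0.50 and 0.59 with an estimated correlation). LTV1, needed to export small ribosomal subunits (XI, 176781 to 178172), fell by 3.29 at 30 min and ENP2, a small-subunit processing factor (VII, 781767 to 783890), by 3.17. Of 137 ribosomal protein genes, 117, 112 and 113 fell at 30, 60 and 120 min (121, 114 and 115 adjusted over the list alone), with medians of -0.55, -0.59 and -0.56 (adjusted p = 0.35, 0.47 and 0.42 with an estimated correlation). RPS26B (V, 423952 to 424311) fell by 1.36 at 30 min. The ceiling on reads per base may have added to falls of abundant genes, since most later WT libraries were deeper than those at 0 min. With the occupancy correction all 95 list results stayed on the same side of the threshold at the preset correlation. The corrected medians of these lists are not given here.

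Of 59 targets of the stress factors Msn2 and Msn4, 41 rose and 1 fell at 30 min, 32 and 6 at 60 min, and 38 and 2 at 120 min (42 and 1, 32 and 6, 38 and 2 adjusted over the list alone), with medians of 0.75, 0.53 and 0.67 (adjusted p = 0.35, 0.51 and 0.42 with an estimated correlation). CTT1, the cytosolic catalase, rose by 1.81 at 30 min and GRE1, a hydrophilin, by 2.53, while HSP30, a plasma membrane stress protein, fell by 2.58. The median level of the stress list was 7.40, 7.27 and 8.07 log2(RPKM + 1) in WT 30 min replicates 1, 2 and 3. Of 30 glucose-repressed and gluconeogenic genes, 19, 18 and 16 rose and 3, 2 and 2 fell (the same numbers adjusted over the list alone), with medians of 0.73, 0.70 and 0.70 (adjusted p = 0.35, 0.47 and 0.42 with an estimated correlation). CRC1, the mitochondrial carnitine carrier, rose by 3.56, 4.23 and 4.28, and HXT5, a hexose transporter of slow growth, by 3.19, 3.49 and 4.29. Of 35 genes of autophagy and vacuolar proteolysis, 24 rose at each time and 0, 2 and 2 fell (25 and 0, 26 and 2, 25 and 2 adjusted over the list alone), with medians of 0.64, 0.68 and 0.56 (adjusted p = 0.22, 0.46 and 0.42 with an estimated correlation). ATG36, a receptor for degrading peroxisomes, rose by 1.39, 1.46 and 1.66.

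**Figure D2:**
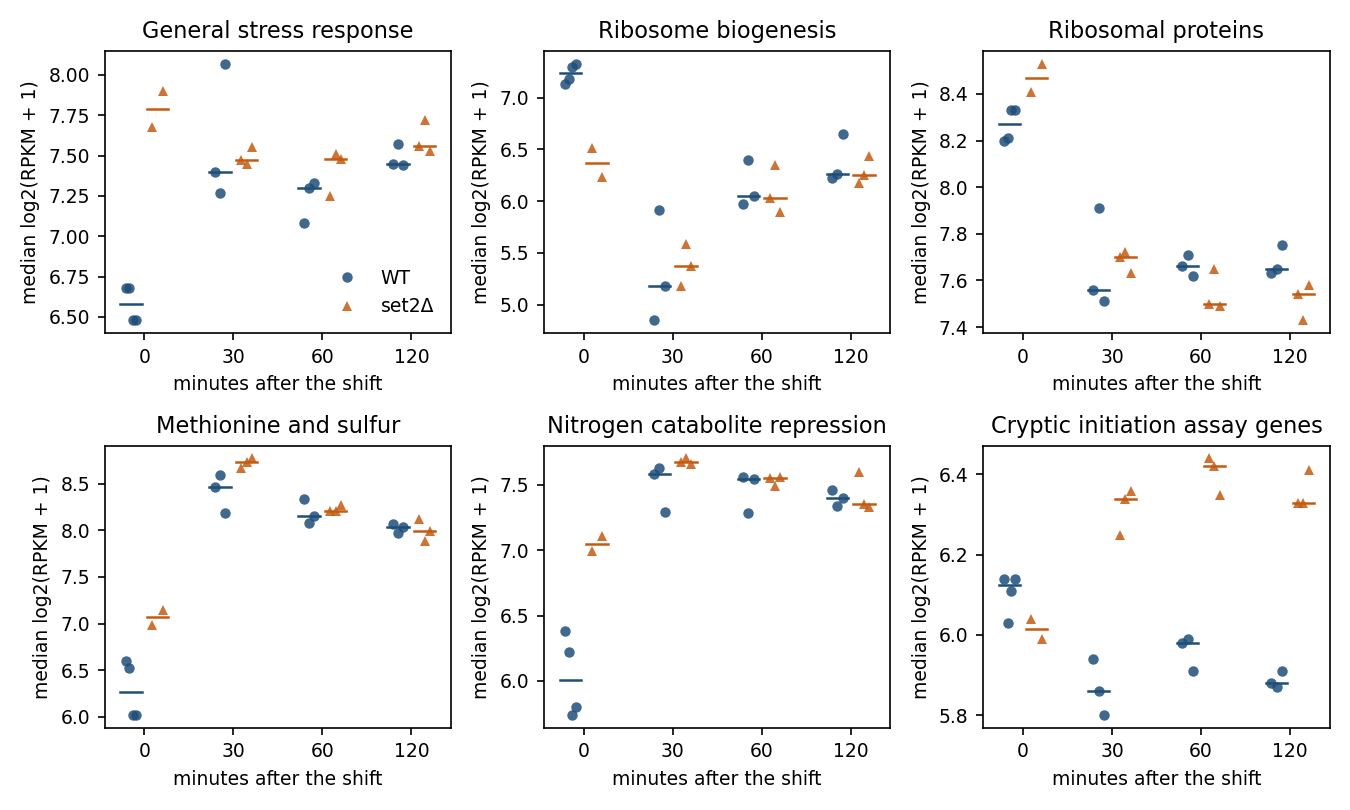
Median log2(RPKM + 1) of 6 gene lists in each library (vertical axes, each panel with its own range) against minutes after the shift, circles for WT and triangles for set2Δ, with a bar at the median of each group's libraries. The stress list median was 6.48 to 6.68 in the WT libraries and 7.68 and 7.90 in the set2Δ libraries at 0 min, and the cryptic initiation panel shows set2Δ above WT in every library after the shift.

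Genes that only MATa cells normally express rose in these cultures of a MATα strain. MFA2, an a-factor precursor (XIV, 352414 to 352530), went from 6.9 ± 2.3 RPKM (SD, n = 2) at 0 min to 449 ± 38.8 RPKM (SD, n = 3) at 60 min in WT, a log2 change of 5.86 ± 0.70 (SE, adjusted p = 2.3e-06, limma). STE2, the receptor for α-factor, went from 16.7 ± 0.9 to 321 ± 25.9 RPKM, AGA2, the a-agglutinin subunit, from 20.3 ± 4.4 to 362 ± 24.5 RPKM, and BAR1, the protease that degrades α-factor, from 18.2 ± 2.4 to 193 ± 23.3 RPKM (SD, n = 2 and 3). All 8 tested genes of the a-cell list rose at 60 min and at 120 min (8 and 8 adjusted over the list alone), with medians of 4.14 and 3.84 (camera adjusted p = 3.4e-05 and 8.5e-05, adjusted p = 0.47 and 0.42 with an estimated correlation). MFA1 rose by 4.64 at 60 min, ASG7 by 6.16, STE6, the a-factor exporter, by 2.23. The list also held AXL1, a protease gene expressed in both haploid cell types, which stood at 85.7 ± 2.4 RPKM (SD, n = 2) at 0 min and rose by 0.82. ASG7 (X, 101150 to 101779) is a neighbour of SET2. YNL146C-A, a frame close to MFA2 (XIV, 351386 to 351580), was listed at 0 in WT at 0 min and at 107 ± 21.6 RPKM (SD, n = 3) at 60 min. PRM6, a potassium channel gene induced by pheromone (XIII, 180017 to 181075), rose by 5.16.

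At 30 min 6 of the 8 genes of the list rose (6 adjusted over the list alone) with a median of 1.96 (camera adjusted p = 0.01, adjusted p = 0.54 with an estimated correlation), and the libraries of that group differed widely. STE2 was at 269, 147 and 24.6 RPKM in WT 30 min replicates 1, 2 and 3, and MFA2 at 343, 163 and 23.5 RPKM, while GAP1 was at 351, 422 and 464 RPKM in the same libraries. Of the genes that α cells normally express, MF(ALPHA)2 fell at 30 min by 0.74 in WT and by 0.62 in set2Δ, and SAG1, α-agglutinin, fell by 0.26 in WT. MF(ALPHA)1 was at 394 ± 18.9 RPKM (SD, n = 2) in WT at 0 min and 362 ± 16.1 RPKM (SD, n = 3) at 60 min, with a log2 change of -0.12 that did not pass the test. MF(ALPHA)2, STE3, the a-factor receptor, and SAG1 rose by 0.23, 0.51 and 0.62 at 60 min, so 3 of 4 α-cell genes rose (3 adjusted over the list alone, median 0.37, adjusted p = 0.5 with an estimated correlation). In set2Δ all 8 genes of the a-cell list rose at 30, 60 and 120 min (8 at each adjusted over the list alone), with medians of 2.53, 4.06 and 3.95 (adjusted p = 0.44, 0.40 and 0.44 with an estimated correlation). AGA2 rose by 5.29 and BAR1 by 4.38 at 60 min in set2Δ. Between the genotypes at 60 min, no gene of this list passed the test, with log2 differences from -0.80 for ASG7 to 0.06 for STE6. The spread used in that test also holds the WT 30 min libraries, so differences in these genes could be missed. ASG7 was at 137 to 180 RPKM in WT and at 77.1 to 117 RPKM in set2Δ at 60 min. AGA2, MFA2 and AXL1 were also lower in every set2Δ library, while MFA1, STE2, STE6 and BAR1 overlapped between the genotypes. At 0 min AGA2, which passed the test there, stood at 20.3 ± 4.4 RPKM in WT and 6.6 ± 0.3 RPKM in set2Δ (SD, n = 2 each). BAR1 stood at 18.2 ± 2.4 and 7.3 ± 0.4 RPKM, while the means of MFA1, MFA2, STE2 and ASG7 were higher in set2Δ.

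**Figure D3:**
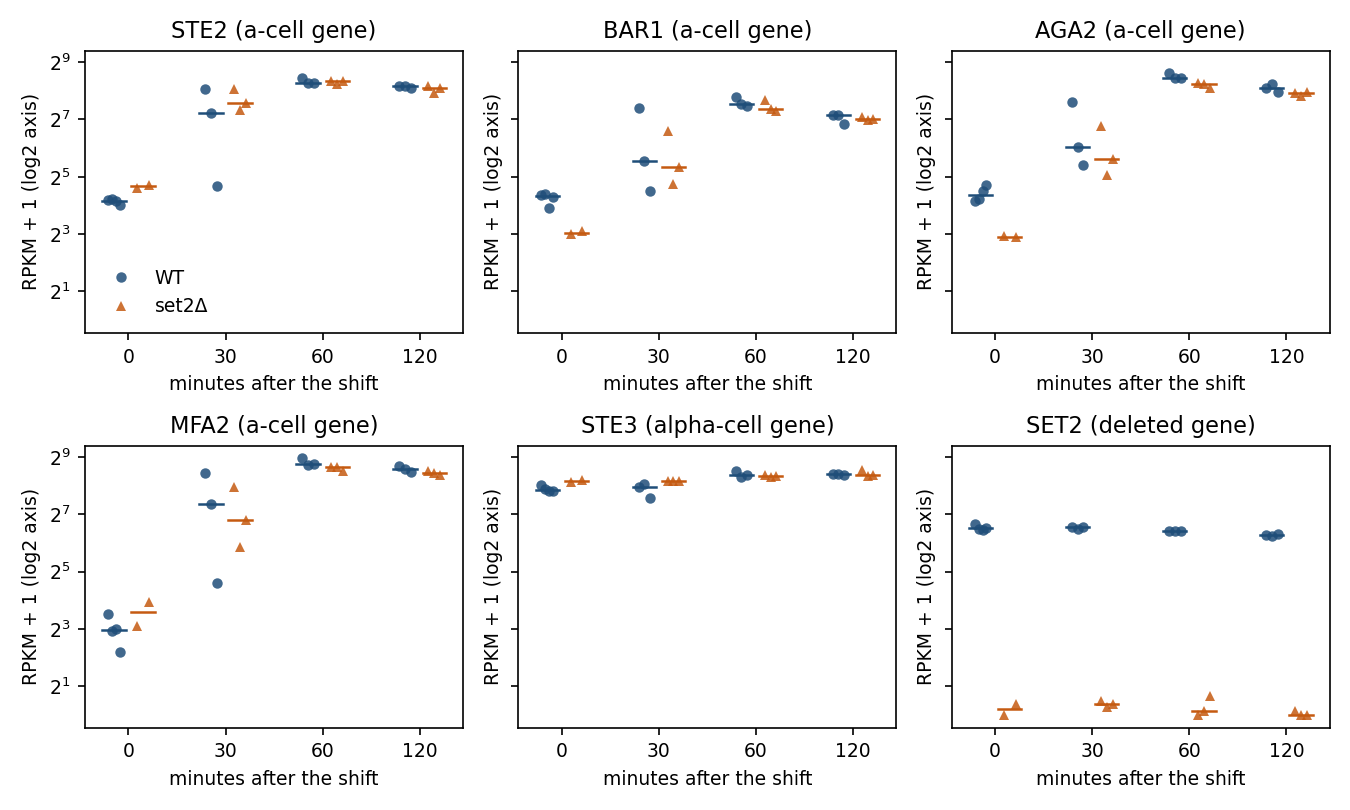
RPKM + 1 on a log2 axis for 4 a-cell genes, the α-cell gene STE3 and SET2 in each library, against minutes after the shift, circles for WT and triangles for set2Δ, with a bar at the median of each group's libraries. STE2 lay between 15.3 and 25.3 RPKM in the 0 min libraries and between 300 and 351 RPKM in the 60 min libraries, while WT at 30 min replicate 3 was at 24.6 RPKM.

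Among the largest decreases in WT were frames without a gene symbol. The names of some, such as YKL156C-A and YAL037C-B, place them opposite another gene. YKL156C-A stood at 112 ± 27.5 RPKM (SD, n = 2) in WT at 0 min and at 0.6 ± 1.1 RPKM (SD, n = 3) at 30 min, and YLR149C-A at 73.4 ± 7.8 and 1.8 ± 3.0 RPKM. YPL142C fell by 5.04 and YAL037C-B by 4.67 at 30 min (5.28 without WT 30 min replicate 3), and LSO1, a small gene linked to the iron response (X, 448477 to 448758), fell by 4.70 at 60 min. In 32 frames named opposite another gene, chosen after the data were seen and low outside WT at 0 min by that choice, the level was 2.96%, 6.87%, 6.11% and 5.92% of that of the facing gene in the 4 WT 0 min libraries and 0.74% to 3.36% in the other 20. Without level limits the same comparison over 166 frames gave 58.0% to 61.3% in WT at 0 min and 53.6% to 60.0% elsewhere, which overlap.

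The same time changes in set2Δ answered whether cells without Set2 mount the response. Most ribosomal protein genes fell and many nitrogen and sulfur genes rose, while more stress genes fell than rose. DAL80 rose by 5.72, 5.84 and 5.74, SEO1 by 4.05 at 30 min, SUL1, a sulfate permease, by 3.43 at 30 min and MET8, an enzyme of siroheme synthesis, by 3.41. limma called 2660 genes at 30 min (1399 up, 1261 down), 3130 at 60 min (1611 up, 1519 down) and 3337 at 120 min (1649 up, 1688 down). Between genotypes, which share no library in these contrasts, the changes correlated across genes (Pearson r = 0.65, 0.63 and 0.63, genes not being independent replicates). At 60 min 1015 genes rose in both genotypes against 447 for independent lists, 990 fell in both against 499, and 145 were called in opposite directions.

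Of 137 ribosomal protein genes, 130, 131 and 132 fell in set2Δ at 30, 60 and 120 min (130, 132 and 132 adjusted over the list alone), with medians of -0.76, -0.91 and -0.93 (adjusted p = 0.32, 0.40 and 0.44 with an estimated correlation). Of 78 ribosome biogenesis genes 56, 20 and 11 fell and 0, 5 and 8 rose (66, 19 and 9 fell and 0, 5 and 3 rose adjusted over the list alone), with medians of -1.05, -0.29 and -0.19 (adjusted p = 0.44, 0.82 and 0.85 with an estimated correlation). KRR1, a small-subunit processing factor, fell by 2.48, 1.25 and 1.08. In nitrogen catabolite repression 19 of 33 rose at each time and 3, 6 and 6 fell (19 rose and 4, 6 and 7 fell adjusted over the list alone), with medians of 0.90, 0.74 and 0.64 (adjusted p = 0.32, 0.40 and 0.45 with an estimated correlation). Methionine and sulfur genes rose in 22, 19 and 13 of 27 cases and fell in 0, 4 and 4 (23, 19 and 13 rose and 0, 4 and 4 fell adjusted over the list alone), with medians of 1.13, 0.81 and 0.38 (adjusted p = 0.32, 0.40 and 0.50 with an estimated correlation). Of 56 amino acid genes 36, 33 and 31 rose and 3, 5 and 6 fell (43, 37 and 32 rose and 3, 5 and 6 fell adjusted over the list alone), with medians of 0.53, 0.49 and 0.42 (adjusted p = 0.44, 0.57 and 0.63 with an estimated correlation). AGP1, an amino acid permease of rich medium, fell by 2.35 at 60 min. Of 59 stress genes 10, 6 and 8 rose and 18, 25 and 22 fell (11, 6 and 8 and 18, 25 and 22 adjusted over the list alone), with medians of -0.07, -0.34 and -0.22 (adjusted p = 0.91, 0.70 and 0.85 with an estimated correlation). HSP30 fell by 3.98, 4.20 and 3.40 and GRE1 rose by 2.17, 2.01 and 2.04.

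Before the shift, set2Δ already differed from WT. Many stress genes were higher in set2Δ: FMP45, a cell cortex protein of stationary phase, stood at 50.9 ± 33.7 RPKM in WT and 255 ± 11.7 RPKM in set2Δ (SD, n = 2 each), DDR2, a multi-stress gene, at 115 ± 11.4 and 389 ± 26.1 RPKM, and ALD3, an aldehyde dehydrogenase, at 21.3 ± 9.8 and 79.4 ± 1.5 RPKM. Some ribosome biogenesis genes were lower: MAK16, a large-subunit factor (I, 100225 to 101145), stood at 205 ± 25.5 and 33.0 ± 9.1 RPKM, and REI1, a cytoplasmic large-subunit factor (II, 739841 to 741022), at 139 ± 17.5 and 36.1 ± 15.8 RPKM. The log2 differences were 2.48, 1.75, 1.92, -2.62 and -1.98 in that order, with adjusted p (limma) of 5.7e-05, 1.2e-07, 9.4e-06, 0.00047 and 5.6e-05. The comparison called 2789 genes, 1024 higher and 1765 lower in set2Δ, and from 1667 to 3515 over all alternatives. The median over all genes was -0.10 as deposited and 0.01 with median-ratio scaling, which called 1505 higher and 1298 lower of 2803, so the excess of lower calls depended on the scaling. Over the 166 opposite-strand frames without level limits, the ratio given above was 58.0% to 61.3% in the WT libraries at 0 min and 57.9% and 55.2% in the set2Δ libraries.

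Of 59 stress genes, 41 were higher and 2 lower at 0 min (44 and 3 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 6.1e-20, adjusted p = 0.44 with an estimated correlation). Of 51 genes of the tricarboxylic acid cycle and respiration, 39 were higher and 1 lower (39 and 1 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.44 with an estimated correlation). SDH2, a succinate dehydrogenase subunit (XII, 53131 to 53931), stood at 91.4 ± 8.1 and 172 ± 7.2 RPKM (SD, n = 2 each). Methionine and sulfur genes were higher in 21 of 27 cases and lower in 2 (22 and 2 adjusted over the list alone, median 0.91, adjusted p = 0.44 with an estimated correlation). STR3, cystathionine beta-lyase, was higher by 2.50 ± 0.41 (SE). Of 56 amino acid genes 26 were higher and none lower (27 and 0 adjusted over the list alone, median 0.38, adjusted p = 0.63 with an estimated correlation). SNO1 stood at 4.6 ± 2.6 and 74.4 ± 7.3 RPKM (SD, n = 2 each). In nitrogen catabolite repression 18 of 33 were higher and 4 lower (19 and 5 adjusted over the list alone, median 0.52, adjusted p = 0.60 with an estimated correlation). PUT4, a proline permease, was higher by 2.73 and GAP1 by 2.24.

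Of 78 ribosome biogenesis genes, 41 were lower at 0 min and none higher (44 and 0 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 1.5e-06, adjusted p = 0.68 with an estimated correlation). Of 28 genes of RNA polymerases I and III, 18 were lower and 1 higher (18 and 1 adjusted over the list alone, median -0.66, adjusted p = 0.63 with an estimated correlation). RRN11, a polymerase I initiation factor, was lower by -2.15 ± 0.35 (SE). Ribosomal protein genes went the other way, with 41 of 137 higher and 1 lower (35 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.64 with an estimated correlation). That call was lost with quantile normalization, where the median was 0.04. Genes named by size included COX26, a cytochrome oxidase subunit (IV, 691014 to 691214), at 11 ± 8.3 and 138 ± 19.9 RPKM, and YNR064C, an epoxide hydrolase gene (XIV, 749136 to 750008), at 4.4 ± 1.2 and 58.8 ± 0.1 RPKM (SD, n = 2 each). Frames at the lower end, such as YLR149C-A and YFL031C-A, were listed at 0 in both set2Δ libraries and stood at 73.4 ± 7.8 and 24.8 ± 2.4 RPKM in WT (SD, n = 2).

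After the shift, a smaller and recurring set of genes separated the genotypes. PUL3, a pulcherrimin transporter gene (XIV, 744360 to 745343), was higher in set2Δ by 3.37, 4.06 and 4.85 at 30, 60 and 120 min and by 3.49 at 0 min, and at 120 min stood at 1.2 ± 0.3 RPKM in WT and 61.1 ± 1.8 RPKM in set2Δ (SD, n = 3 each, adjusted p = 5.6e-09, limma). OPT2, an oligopeptide transporter gene (XVI, 924304 to 926937), was higher by 3.19 at 0 min and by 1.59, 2.47 and 2.47 later. COS10, a subtelomeric family gene (XIV, 779916 to 781040), was lower by -3.66, -3.58 and -3.67 and ADH7, an alcohol dehydrogenase gene (III, 309070 to 310155), by -3.81, -3.40 and -3.40. Both lie near chromosome ends and have relatives elsewhere in the genome. CDA1, a chitin deacetylase of spore walls (XII, 745620 to 746525), was lower by -3.19 and -3.54 at 60 and 120 min. COS10, ADH7 and CDA1 were called lower in set2Δ at 0 min too.

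limma called 1164 genes at 30 min (266 higher, 898 lower in set2Δ), 744 at 60 min (249 higher, 495 lower) and 844 at 120 min (322 higher, 522 lower). With median-ratio scaling the splits were 505 and 484 of 989, 353 and 299 of 652, and 416 and 314 of 730, so the excess of lower calls depended on the scaling here too. Without WT 30 min replicate 3, an alternative added after the data were seen, 1020 genes were called at 30 min (229 higher, 791 lower), 704 of them with the same direction as before. Over all alternatives the counts ran from 40 (a fit on only the groups compared) to 1840 at 30 min, from 417 to 1671 (array weights) at 60 min and from 524 to 1601 (array weights) at 120 min. At 30 min quantile normalization gave 712 and array weights 580. The comparisons at different times share no library. That does not make them independent, since samples of different times may come from the same cultures. Over all times 16 of 24 libraries correlated best with a library of their own number. Changes at 60 and 120 min correlated across genes with r = 0.84, with 211 genes higher at both times against 12.6 for independent lists, 333 lower at both against 40.5, and none in opposite directions. Between 0 and 120 min r was 0.27, with 73 genes higher at both against 51.6, 252 lower at both against 144, and 92 in opposite directions.

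Genes used in earlier work to assay cryptic initiation, the start of transcription inside genes, were in part higher in set2Δ after the shift. Their choice in the field rests on strains with lost chromatin repression, so their direction is not independent evidence. The values cover whole coding sequences, so they cannot tell starts inside a gene from more full-length RNA. PCA1, a metal-transporting ATPase, stood at 52.0 ± 12 and 121 ± 4.4 RPKM at 30 min, and AVO1, a subunit of TOR complex 2, at 53.8 ± 1.9 and 85.3 ± 4.1 RPKM (SD, n = 3 each). STE11, a mitogen-activated kinase kinase kinase, was higher by 0.45, 0.75 and 0.73 and LCB5, a sphingoid base kinase, by 0.64, 0.73 and 0.59 (adjusted p from 8.8e-05 to 3.1e-07, limma). PCA1, STE11 and LCB5 were called higher in set2Δ at 0 min too. Of 10 genes measured, 4, 5 and 6 were higher and none lower at 30, 60 and 120 min (5 and 2, 5 and 0, 6 and 0 adjusted over the list alone), with medians of 0.20, 0.33 and 0.46. The camera calls (adjusted p = 0.00019, 6.2e-08 and 4.5e-08) were kept with an estimated correlation (adjusted p = 0.016, 0.00065 and 0.0006).

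Of 48 genes of meiosis and sporulation, which haploid cells keep low, 19, 15 and 15 were lower in set2Δ at 30, 60 and 120 min and 2, 2 and 3 higher (20, 18 and 18 lower and 3, 3 and 3 higher adjusted over the list alone). The medians were -0.45, -0.34 and -0.27 (camera adjusted p = 0.0037, 0.008 and 0.12, adjusted p = 0.63, 0.78 and 0.98 with an estimated correlation). MEI4, needed for meiotic double-strand breaks (V, 238460 to 239774), stood at 12.6 ± 1.3 and 0.7 ± 0.6 RPKM at 60 min, DMC1, the meiotic recombinase, at 40.3 ± 1.7 and 7.1 ± 1.7 RPKM, and REC8, a meiotic cohesin subunit, at 8.8 ± 0.7 and 1.5 ± 0.6 RPKM (SD, n = 3 each). GAS4, a spore wall glucanosyltransferase, was lower by -2.61, -2.24 and -2.10 at 30, 60 and 120 min. MEI4, DMC1, REC8 and GAS4 were called lower in set2Δ at 0 min too. At 120 min the list passed with median-ratio scaling (median -0.22) and with quantile normalization (median -0.27).

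Nitrogen genes were higher in set2Δ in 5, 4 and 4 of 33 cases after the shift and lower in 0, 0 and 1 (the same numbers adjusted over the list alone), with medians of 0.19, 0.10 and 0.07 (adjusted p = 0.56, 0.78 and 0.77 with an estimated correlation). Those higher included DAL4, the allantoin permease (IX, 408468 to 410375), by 0.76, 1.07 and 1.23, and PTR2, a dipeptide transporter (XI, 615730 to 617535), by 0.88 and 1.18 at 30 and 120 min. At 30 min 8 of 56 amino acid genes were higher (14 adjusted over the list alone, median 0.26, adjusted p = 0.51 with an estimated correlation). SNZ1 was higher by 1.18, and by 0.53 without WT 30 min replicate 3. Of 27 methionine and sulfur genes 4 were higher at 30 min (3 adjusted over the list alone, median 0.22, adjusted p = 0.51 with an estimated correlation). SUL1 was higher by 0.40. Of 19 purine genes 1, IMD4, was higher at 30 min by 0.61 (none adjusted over the list alone, median 0.22, adjusted p = 0.61 with an estimated correlation). Stress genes were higher in 0, 1 and 1 of 59 cases and lower in 2, 2 and 0 at 30, 60 and 120 min (0, 0 and 1 higher and 2, 2 and 0 lower adjusted over the list alone). Their medians were -0.03, 0.07 and 0.05 (adjusted p = 0.91, 0.99 and 0.98 with an estimated correlation). The stress median at 30 min was 0.06 with median-ratio scaling and 0.13, past the test, without WT 30 min replicate 3. SSA3, an Hsp70 chaperone, was higher by 0.50 at 120 min.

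At 120 min some genes of vitamin and lipid synthesis were lower in set2Δ, and each of the 3 lists had an adjusted p = 0.77 with an estimated correlation. BNA2, the first enzyme of nicotinic acid synthesis, stood at 32.3 ± 4.9 and 7.7 ± 2.4 RPKM, THI2, an activator of thiamine genes, at 29.1 ± 5.3 and 8.6 ± 2.2 RPKM, and THI4, of thiamine synthesis, at 51.8 ± 8.2 and 17.9 ± 6.5 RPKM (SD, n = 3 each). Of 29 vitamin genes 11 were lower and 1 higher (13 and 2 adjusted over the list alone, median -0.33, adjusted p = 0.77 with an estimated correlation). Of 26 ergosterol genes 7 were lower (8 adjusted over the list alone, median -0.10, adjusted p = 0.77 with an estimated correlation). HMG1, an HMG-CoA reductase, was lower by -0.50. The ergosterol call was lost with median-ratio scaling, where the median was -0.03. Of 18 phospholipid genes 3 were lower (6 adjusted over the list alone, median -0.16, adjusted p = 0.77 with an estimated correlation). CKI1, choline kinase, was lower by -0.40.

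Averaged over the 4 times, limma called 3197 genes, 924 higher and 2273 lower in set2Δ, against 1664 and 1426 of 3090 with median-ratio scaling. AVO1 was higher by 0.57 ± 0.04 and LCB5 by 0.56 (SE where given). Of the 10 cryptic initiation genes 6 were higher and 3 lower (6 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.042 with an estimated correlation). Of 48 TOR pathway genes 10 were higher and 17 lower (10 and 17 adjusted over the list alone). CRF1, a repressor of ribosomal protein genes, was lower by -0.38. Of 44 genes of the Set2 and Rpd3S pathway and cotranscriptional chromatin factors 8 were higher and 16 lower (8 and 16 adjusted over the list alone). DOT1, the H3K79 methyltransferase, was lower by -0.39. Neither list passed camera (median -0.07 each while camera's direction was up, adjusted p = 0.91 and 0.97 with an estimated correlation), and both medians turned positive with median-ratio scaling (0.01 and 0.02). There were 53 genes higher and 162 lower in set2Δ at all 4 times.

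Coding length went with the difference between genotypes after the shift. The Spearman correlation of coding length with the set2Δ minus WT change across 5775 genes was 0.02, 0.18, 0.33 and 0.29 at 0, 30, 60 and 120 min, and genes are not independent replicates. At 60 min 39 of 182 genes over 4000 bp were higher and 4 lower, and 16 of 1444 genes of 500 to 1000 bp were higher and 194 lower, with medians of 0.08 and -0.14. At 0 min 49 genes over 4000 bp were higher and 17 lower, and 241 genes of 500 to 1000 bp were higher and 443 lower. The medians there were 0.06 and -0.12, so these 2 bins differed in the same direction before the shift. Coding length was singled out after 84 correlations with length, mean level and GC content had been looked at, of which level correlated more strongly at 0 and 30 min (0.46 and 0.34). Leaving out each library in turn gave 0.29 to 0.35 at 60 min. Among genes not in RefSeq R64, 65.5% of called genes were higher in set2Δ at 60 min, against 30.8% of the others (Fisher's exact test, 2-sided, p = 3.0e-07 across genes), and at 0 min 33.2% and 37.0% (p = 0.29).

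**Figure D4:**
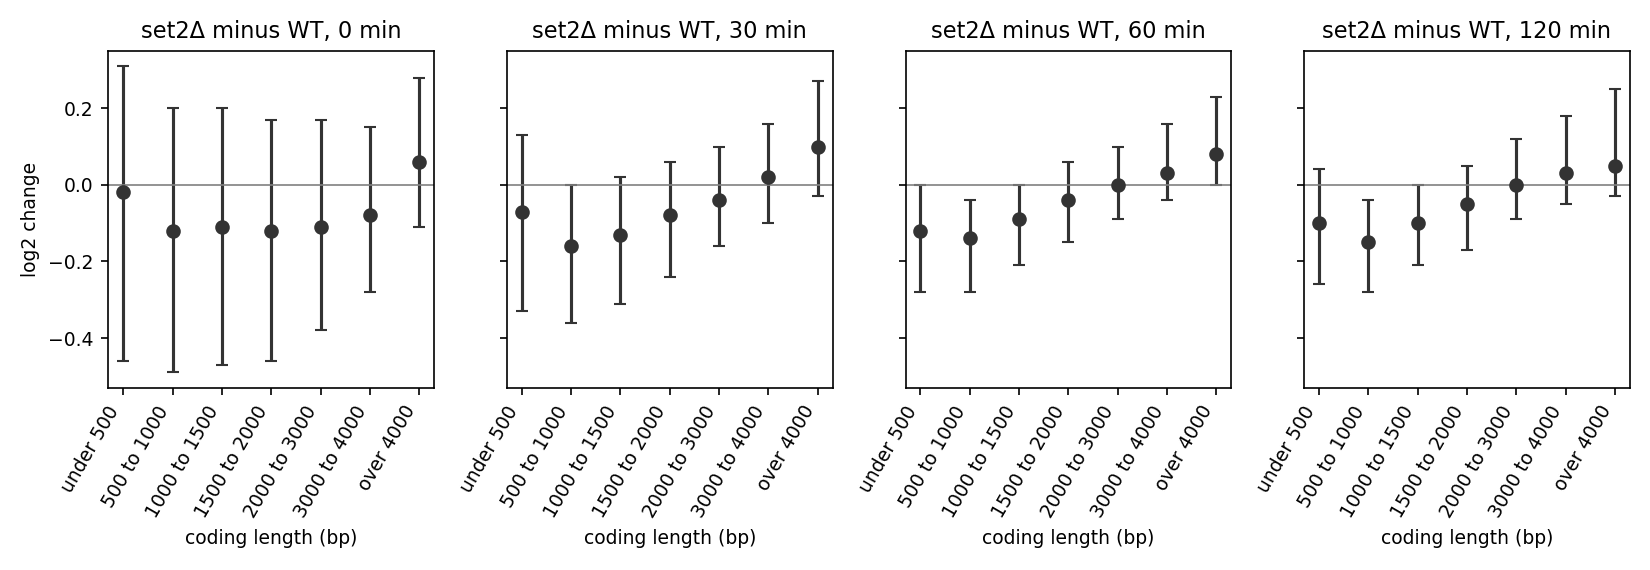
Log2 change, set2Δ minus WT, by bins of coding length in bp (horizontal axis) at 4 times, where points are medians over genes and bars run from the lower to the upper quartile of genes. At 60 min the median went from -0.14 at 500 to 1000 bp to 0.08 over 4000 bp, and at 0 min it was -0.12 and 0.06.

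The interaction answered whether the time change differed between genotypes. It differed for 1077 genes at 30 min (522 up, 555 down), 1708 at 60 min (928 up, 780 down) and 1894 at 120 min (1014 up, 880 down). The stress list fell relative to WT, with 41, 33 and 34 of 59 genes lower in the interaction and 1, 2 and 2 higher (46, 40 and 40 and 2, 2 and 3 adjusted over the list alone). HSP26, a small heat shock protein, was at -2.12, -1.97 and -1.82. The ribosome biogenesis list went the other way, with 27, 27 and 23 of 78 higher (33, 37 and 23 adjusted over the list alone). BFR2, a small-subunit processing factor, was at 2.23, 2.10 and 2.12. The medians were -0.94, -0.83 and -0.81 for stress (adjusted p = 0.29, 0.52 and 0.45 with an estimated correlation) and 0.81, 0.79 and 0.69 for ribosome biogenesis (adjusted p = 0.60, 0.52 and 0.57). As given above, the stress list was higher in set2Δ at 0 min, while few of its genes differed between the genotypes after the shift. The interaction of the stress list thus largely carries the 0 min difference. Every interaction uses the 0 min groups, with n = 2 each. At 30 min the count was 161 in a fit on only the groups compared, 408 without set2Δ 0 min replicate 2, 409 without WT 0 min replicates 3 and 4, and 1891 without WT 30 min replicate 3. Over all alternatives it ran from 824 to 2804 at 60 min and from 1015 to 2898 at 120 min.

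The other fixed lists gave the following for WT at 60 min and then for set2Δ minus WT at 60 min, with the count adjusted over the list alone after each pair. Of 40 genes of translation factors and tRNA synthetases 24 fell in WT (24) and 1 was lower in set2Δ (0), of 11 pyrimidine genes 3 rose and 5 fell (3 and 5) and 3 were lower (3). Of 15 amino acid permeases of rich medium 3 rose and 6 fell (3 and 6) and 2 were higher and 1 lower (3 and 3). Of 18 glycolytic genes 3 rose and 5 fell (3 and 4) and 2 were lower (2). Of 17 hexose transporters 2 rose and 8 fell (2 and 8) and 1 was lower (1). In the phosphate regulon of 20 genes 8 rose and 3 fell (8 and 3) and 2 were lower (2). In the iron regulon of 25 genes 8 rose and 10 fell (8 and 11) and 4 were higher and 3 lower (4 and 3). In the zinc regulon of 14 genes 4 rose and 3 fell (4 and 3) and 1 was higher and 1 lower (1 and 2). Of 11 histone genes 4 fell (4) and none differed by limma. Of 40 cell cycle regulators 7 rose and 22 fell (7 and 22) and 4 were higher and 3 lower (6 and 3). Of 38 cell wall integrity genes 7 rose and 11 fell (7 and 11) and 2 were higher and 1 lower (2 and 0). Of 42 cytosolic chaperone and proteasome genes 2 rose and 26 fell (2 and 26) and none differed between genotypes by limma. The estimated-correlation adjusted p of these lists ran from 0.14 for the iron regulon to 0.99 in set2Δ minus WT, and from 0.47 to 0.93 in WT. The 8 mitochondrially encoded genes fixed as a list matched no name in the table.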

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

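All tests weighed in this part were chosen after the results were seen, except the splits of libraries into other groups and the test of RNA integrity, which were written before. The counts, gene groups and single genes listed first were taken up because a test of the interaction found the time change to differ between set2Δ and WT. The 3 patterns weighed after them were not taken up by that test but chosen after the results were seen. The rule for a library far from its group was not applicable, since no group had 4 samples. The interaction called 1077 genes at 30 min, 1708 at 60 min and 1894 at 120 min.

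The gene groups that differed are given as medians of the interaction, the time change in set2Δ less that in WT, at 30, 60 and 120 min. They were stress genes (-0.94, -0.83 and -0.81, adjusted p = 0.29, 0.52 and 0.45 with an estimated correlation), respiration genes (-0.42, -0.49 and -0.52, adjusted p = 0.29, 0.26 and 0.22) and ribosome biogenesis genes (0.81, 0.79 and 0.69, adjusted p = 0.60, 0.52 and 0.57). The same held for ribosomal protein genes (-0.21, -0.32 and -0.35, adjusted p = 0.62, 0.52 and 0.48 with an estimated correlation), methionine and sulfur genes (-0.68, -0.93 and -1.0, adjusted p = 0.56, 0.52 and 0.45) and amino acid genes (-0.11, -0.34 and -0.39, adjusted p = 0.67, 0.52 and 0.48). In the interaction at 30, 60 and 120 min, 28, 36 and 40 of 51 respiration genes were lower and none higher (34, 41 and 40 adjusted over the list alone). Also 12, 34 and 42 of 137 ribosomal protein genes were lower and 1, 1 and 1 higher (4, 32 and 55 lower adjusted over the list alone). Likewise 10, 19 and 20 of 27 sulfur genes were lower and 2, 2 and 1 higher (12, 20 and 21 lower adjusted over the list alone), and 9, 18 and 19 of 56 amino acid genes were lower (6, 19 and 19 adjusted over the list alone). With quantile normalization the 30 min calls of the ribosomal protein and amino acid lists were lost (medians -0.05 and -0.10).

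The genes with the largest interaction at 30 min were YLR149C-A (6.07), YJR151W-A (5.44), YKL156C-A (5.30), YBL071C-B (5.16) and YPL142C (5.01) at one end and CPP3 (-3.42), YHR022C (-3.34), YPR160W-A (-3.27), ECM12 (-3.23) and YNL194C (-3.17) at the other. At 60 min they were YBL071C-B (6.96), YKL156C-A (6.33), YLR149C-A (6.21), YMR307C-A (6.05) and YPL044C (5.11), and COX26 (-3.65), SNO1 (-3.60), YPR160W-A (-3.40), YHR022C (-3.37) and ECM12 (-3.15). At 120 min they were YKL156C-A (6.46), YMR307C-A (6.30), YLR149C-A (6.21), YBL071C-B (5.62) and YPL044C (5.26), and YPR108W-A (-4.29), SNO1 (-3.74), COX26 (-3.64), YPR160W-A (-3.52) and YHR022C (-3.10). Without WT 30 min replicate 3, the 30 min values were 6.95 for YLR149C-A and -2.52 for YNL194C. Where a gene was listed at 0 in a whole group, the fitted value depends on the pseudocount and is no bound on the real difference.

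The first pattern weighed was the difference between set2Δ and WT at 0 min, on which every interaction rests. After the occupancy correction the stress list median was 1.03, which argues against depth and the ceiling on reads per base as the cause. Against each pair of WT libraries alone it was at least 0.78 (0.78 and 0.89), which argues against 1 pair alone. A library or culture batch of WT at 0 min cannot be told apart from an effect of the deletion, since the labels name no batch and the ratio of the 166 opposite-strand frames, at 58.0% to 61.3% in WT at 0 min and 53.6% to 60.0% elsewhere, overlapped. An effect of the SET2 deletion in rich medium stays open as well.

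The second pattern was the rise of a-cell genes in a MATα strain, in both genotypes. LYS2 had 0 reads after the shift, which argues against cells of a MATa strain that carries LYS2. The test set for MATa cells that carry SET2 could not decide, although SET2 in set2Δ was at most 0.6 RPKM after the shift. It needed a lower bound on the share of such cells, which the ceiling on abundant genes removes. SET2 had 6, 6 and 1 reads in set2Δ at 30, 60 and 120 min, against 2071, 2142 and 1966 in WT. STE2 had 2700, 4823 and 3823 reads in set2Δ, against 2310, 4792 and 4213 in WT, and every gene of the a-cell list rose in set2Δ. These values argue against such cells as the main source in the set2Δ libraries. The lowest 60 min library lay 3.54 above the highest 0 min library in the list median, against a limit of 2 set for MATa cells doubling every 30 min. That limit takes the level of these genes per cell as fixed, which was not measured, so it cannot exclude multiplying MATa cells. The rise in set2Δ at 30 min was 2.58 after the occupancy correction, which argues against the ceiling. MATa cells without LYS2 (and, in set2Δ, without SET2) stay open. Loss of the repression that the α2 protein exerts on these genes stays open too, as a hypothesis that was not tested.

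The third pattern was that longer genes were higher in set2Δ after the shift, taken up after the data were seen in place of WT 30 min replicate 3. Genes over 4000 bp differed in this direction from those of 500 to 1000 bp at 0 min as well. The correlation at 60 min was 0.33 after the occupancy correction and 0.34 with mean level held fixed, which argues against the ceiling and against expression level. RNA integrity differing between the genotypes cannot be told apart from an effect of the deletion. After the occupancy correction, the correlations below and above the median level were 0.29 and 0.12 at 30 min and 0.38 and 0.29 at 60 min. At 120 min they were 0.32 and 0.31, an excess of only 0.01, and without the correction 0.32 and 0.28. The test was written before the data were examined, but the correction used in it was added after. A role of Set2 in transcription along genes stays open as a hypothesis.

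For the counts between genotypes, the real split of the 6 libraries was the only 1 of 10 to call as many genes at 30 min (1164, highest other 27), 1 of 10 at 60 min (744, highest other 0) and 1 of 10 at 120 min (844, highest other 0), which are too few splits for a share under 0.05. At 120 min, where the numbers pair the libraries, 4 of the 10 splits part all 3 pairs, the real one among them, and the other 3 of these and the 6 that part 1 pair called 0 genes by limma. For the mean of the 4 times the real labels were the only 1 of 100 to reach 3197 genes (highest other 1323), which argues against a chance draw of the labels. Every draw that called a gene kept the 0 min libraries of each genotype together, and draws that parted them called 0 genes. Part of the 3197 calls can thus rest on the 0 min difference.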

How the results depend on the processing

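The 24 separate libraries, voom, the occupancy correction, the block within 120 min and the fits without WT 30 min replicate 3 were chosen after the results were seen. All 14 counts stayed within 1.5 times under the pseudocounts, the filters, no trend, median-ratio scaling, voom, the 24 libraries and the occupancy correction. With quantile normalization set2Δ minus WT at 30 min had 712 genes instead of 1164. With array weights it had 580, and the counts were 1671 at 60 min (main 744), 1601 at 120 min (844), and 2804 and 2898 for the interaction at 60 and 120 min (1708 and 1894). Fits on only the groups compared gave 40 at 30 min and 1183 at 60 min for set2Δ minus WT, 1076 for WT at 30 min (3229), and 161 and 2729 for the interaction at 30 and 60 min (1077 and 1708). The main fit shares 1 spread per gene over the 8 groups. Pairs of WT 30 min libraries differed by 10.6 to 21.91 in chi-square per gene, against at most 4.44 within any other group. The main fit can thus understate the error of comparisons with WT at 30 min and overstate that of the others. How far this set the counts was not tested. SAG1 at 0 min reversed with quantile normalization (-0.20, against 0.01).

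Leaving out each library in turn gave set2Δ minus WT 1667 to 2295 genes at 0 min (main 2789), 656 to 1840 at 30 min, 417 to 510 at 60 min and 524 to 644 at 120 min. It gave the interaction 408 to 1891 genes at 30 min, 824 to 1577 at 60 min and 1015 to 1824 at 120 min. The other 7 counts ranged from 2752 to 3648 for the mean of the 4 times, from 2154 to 3929 for WT and from 1834 to 3078 for set2Δ. Where 1 sample of a group was left, it was assumed to vary like the other groups.

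Of 705 results of named genes, quantile normalization kept 668 (14 lost and 22 gained a call), median-ratio scaling 694 (5 and 6), voom 688 (8 and 9), the occupancy correction 692 (7 and 6), array weights 660 (7 and 38) and only the groups compared 596 of 680 (55 and 29), since the other 25, for the mean of the 4 times, use every group. At 0 min AGA2 lost its call with quantile normalization (-1.02) and MF(ALPHA)1 with median-ratio scaling (-0.18), while STE3 and HIS3 gained one (0.39 and 0.39). STE3 at 30 min lost its call with quantile normalization (0.26). Of 95 list results, quantile normalization kept 88 and median-ratio scaling 93. The stress list lost its call under quantile normalization for set2Δ minus WT at 60 and 120 min (0.13 and 0.09) and for set2Δ at 60 min (-0.17).

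Over all times, libraries with the same number correlated from -0.22 to 0.33 in their deviations (median 0.04, 77 pairs), others from -0.27 to 0.24, and 16 of 24 matched best with their own number. Set2Δ minus WT at 120 min, taken as paired, had 821 genes with the number as a block within 120 min (main 844, 790 called in both with the same direction). That block left the 7 list results on the same side of the threshold and changed 2 of 57 results of named genes, both gained (OPI1, -0.25, and PIG2, 0.40). With the replicate number as a block, set2Δ minus WT had 3168, 1375, 871 and 980 genes at 0, 30, 60 and 120 min, and no count moved by more than 1.5 times. Depth of 2201243 to 4519162 reads and the ceiling near 2 reads per base limit small changes in low and in very abundant genes.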

Other observations

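The pheromone response list was written after the data were seen, and its tests were chosen then. In WT, 23 of 28 genes rose and none fell at 60 min (median 1.19, p = 0.018 with an estimated correlation), and 23 rose at 120 min (median 1.15, p = 0.019 with an estimated correlation), against 11 up and 1 down at 30 min (median 0.12, p = 0.54 with an estimated correlation). FUS1, needed for cell fusion, stood at 74.9 ± 17.3 RPKM in WT at 0 min (SD, n = 2) and at 291 ± 20.7 RPKM at 60 min (SD, n = 3), KAR4, a transcription factor of karyogamy, at 68.4 ± 19.0 and 319 ± 15.8 RPKM, and PRM1, a membrane fusion protein, at 48.1 ± 6.9 and 353 ± 27.0 RPKM. PRM6 rose by 5.16 and FIG1, a mating gene, by 3.92 in WT at 60 min. In set2Δ 22 genes rose and 1 fell at 60 min (median 1.15, p = 0.037 with an estimated correlation), with PRM6 at 3.87 and FIG1 at 3.07. Between genotypes at 60 min 10 of 28 were lower in set2Δ and none higher (median -0.34, p = 0.097 with an estimated correlation). The interaction at 60 min had 3 genes up and 4 down (p = 0.51 with an estimated correlation). FUS3, a kinase of the pathway, was at 145 ± 12 RPKM in WT and 80.6 ± 9.2 RPKM in set2Δ at 0 min (SD, n = 2 each) and at 273 ± 18.6 and 179 ± 22 RPKM at 60 min (SD, n = 3 each), a rise of 0.90 in WT and 1.14 in set2Δ.

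In WT 30 min replicate 3, with 2201243 reads, SNO1 was at 21.6 RPKM against 183 and 159 RPKM in replicates 1 and 2, and MET17 was at 613 RPKM. In WT at 0 min, GAP1 was at 87.1 and 71.0 RPKM in replicates 1 and 2 and at 21.3 and 24 RPKM in replicates 3 and 4. Replicates 1 and 2, which otherwise differed by less than the sampling noise, were at 2.96% and 6.87% in the ratio of opposite-strand frames, and replicates 3 and 4 at 6.11% and 5.92%. Looser groupings of such frames were looked at before the one given here.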
